A study of Homo sapiens with 9 samples.

How the data were processed

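Total RNA of cultured, sorted human pericytes from 3 tissue sites was measured on Affymetrix whole-transcript arrays labelled with the GeneChip WT PLUS kit, per the labels' protocols. The authors deposited 1 log2 value per probe set and array, made with RMA (background correction, quantile normalization and summary of probes), per the submitters' processing notes. The notes also name Partek and the build hg38; the versions of Partek and RMA are not given in the sources used here. Scanner files were not used here, so the background and normalization steps could not be repeated. The quartiles of the 9 arrays were nearly equal, as quantile normalization leaves them, so a change in total RNA per cell cannot be seen in these values.

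Arrays were grouped by the tissue named in the sample titles, 3 per site, and the replicate number came from the same titles. The labels call them biologic replicates; whether arrays of different sites share a donor is not given in the sources used here. Of 135750 probe sets, 36176 carried 1 gene symbol, 1119 several and 98455 none in the platform annotation, which was updated against a table of RefSeq genes (assembly GRCh38.p14). Of those with 1 symbol, 25516 were matched through an Entrez ID, 9899 by symbol and 623 by an older synonym, and 138 kept the platform's name. For 424 of them the probe set's identifier names another chromosome than the gene's; none of the 81 named genes sits on such a probe set. Probe sets with several symbols or none named no gene. Left out of all testing were 903 probe sets of Y-linked genes, XIST and TSIX, because the samples are human. Each gene was represented by its brightest probe set on average, which gave 33090 genes, 1668 of them with more than 1 probe set.

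The fit was made with limma 3.58.1 in R 4.3.3: 3 group means over all 9 arrays with lmFit and eBayes, 6 residual degrees of freedom and an estimated 2.934 prior degrees of freedom. It gave a moderated F-test of any site difference and contrasts of periosteal against adipose, periosteal against dermal, adipose against dermal, and periosteal against the mean of both soft tissues. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 are said to be called or to pass. Of 31 gene lists, all with at least 5 measured members, camera asked whether members ranked higher or lower than all other genes, with a preset correlation of 0.01 and adjustment over the lists. Members were also counted when adjusted over the list alone. The deposited values were not filtered on level. For overlaps of contrasts that share arrays, 9 arrays with no site difference were simulated 100 times, with errors drawn independently for each gene.

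The grouping, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named up to 8 genes per direction and contrast by largest difference among called genes whose arrays did not overlap; where none was called, the 3 with the smallest p in each direction. It also took up to 4 called members per list and contrast, or the member with the smallest p, and always MCAM, PECAM1, PTPRC, CXCL12 and CXCR4. It named 81 genes; list members named as called over the list alone, the HOXC genes and the genes of the closing observations were chosen after their values were seen.

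The scripts for genes and lists were tested on simulated data with the real genes' means and spread, in 5 runs of 33090 genes. For periosteal against adipose, changes of 1, 2, 3 and 4 on the log2 scale were recovered in 58.4%, 87.6%, 99.2% and 97.6% of 250 genes each, with 43 false calls over the runs. For periosteal against dermal the shares were 56.8%, 88.0%, 99.2% and 98.8%, with 41 false calls. For adipose against dermal, where nothing was changed, there were 0 false calls over the runs. The changed genes were drawn at random and changed together, so the shares do not hold for genes with a wide spread between arrays. In the real data, PRG4 differed by 5.89 between adipose and dermal cells and did not pass. A low count of called genes therefore does not show that large differences are absent. Of 100 unchanged lists, 0 were called in any contrast, and a list of 20 genes shifted by 0.5 in periosteal arrays was called in each contrast that involves them. Errors were drawn independently for each gene, while estimated correlations of the real lists reached 0.732. The simulation therefore does not show how often lists of correlated genes are called by chance. Other splits of the real arrays, described at the end, called a median of 5 or 6 lists per contrast.

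The alternatives were the replicate number as a block, quantile normalization again, centring each array on its median, leaving out dim genes, the mean of a gene's probe sets, all probe sets as features, an intensity trend with a robust prior, ordinary least squares, an absolute log2 difference of at least 1, only the arrays of the sites compared, and leaving out each array in turn. For lists they were camera with an estimated correlation and fry. Array quality weights were added after seeing the data. Scan dates or slides were not used here, so no batch could be tested. The number of arrays limits the precision.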

Results

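Transcript levels were measured in cultured human pericytes, the contractile cells that wrap small blood vessels, from 3 tissue sites: periosteum (the membrane over bone), subcutaneous fat and dermis. Cells had been sorted for the surface protein CD146 and against CD31 (endothelial cells) and CD45 (blood cells), then grown in serum-containing medium until just short of confluence. Each site had 3 biologic replicates with 1 Affymetrix whole-transcript array each, 9 arrays in all; n = 3 arrays per site for every mean below. Values are deposited log2 levels. Array medians ran from 4.60 to 4.63, and Spearman correlations of arrays over all probe sets, which are not independent, were 0.966 to 0.980 within sites and 0.967 to 0.976 between sites. No pair of arrays looked like 1 library deposited again: at most 576 of 135750 probe sets had identical values on both, and the smallest median absolute difference was 0.18. No background level was used here, so a level near or below the array medians is not shown to be above background, and differences from such a level are uncertain in size. The number of arrays limits the precision of every comparison.

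The transcripts behind the sort came first, as the check of the labels that the design offers. PECAM1, which encodes CD31, had mean log2 levels of 5.69 ± 0.12 (SD, n = 3) in periosteal, 5.43 ± 0.28 in adipose and 5.49 ± 0.21 in dermal cells. PTPRC, which encodes CD45, stood at 4.67 ± 0.12, 4.37 ± 0.23 and 4.35 ± 0.14 in the same order, close to the array medians. MCAM, the gene of CD146, shares its probe set TC1100012520.hg.1 with the microRNA gene MIR6756, so this value names neither gene alone. That probe set had levels of 7.54 ± 0.38 in periosteal, 6.58 ± 0.54 in adipose and 7.82 ± 1.10 in dermal cells. The chemokine gene CXCL12 was bright at 9.40 ± 0.49, 9.88 ± 0.44 and 9.69 ± 0.86, and its receptor gene CXCR4 was near 5.04, 5.03 and 5.02. None of these differed between sites by limma (smallest adjusted p = 0.739, for the MCAM and MIR6756 probe set between adipose and dermal cells).

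Across the 3 sites together, 3 genes passed the moderated F-test over 33090 genes, each with adjusted p = 0.0248: KCNT2, a sodium-activated potassium channel subunit; DEPTOR, an inhibitor of the mTOR kinase; and DUXAP8, a transcribed pseudogene. At an unadjusted p under 0.05 there were 2225 genes, 6.72% of those tested. Site accounted for a median of 23.5% of a gene's variance. By chance, 25% is expected for 3 groups of 3 as a mean. For normal errors the median expected by chance is lower than this mean, so 23.5% is not a sign of a share below chance. Whether it lay above chance was not tested. The first 4 principal components held 22.9%, 18.4%, 15.6% and 12.9% of the variance, and 14.5%, 71.4%, 50.7% and 33.6% of each lay between sites. The count was 0 without periosteal replicate 1 and 1 without adipose replicate 2, adipose replicate 3 or dermal replicate 3. It rose to 9 without periosteal replicate 3, 13 without adipose replicate 1, 39 without dermal replicate 1 and 9 without dermal replicate 2. It was 0 without moderation, 5 with an intensity trend and robust prior and 6 over all probe sets.

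Periosteal and adipose cells were compared first. The genes with the smallest p did not pass the test, all with adjusted p = 0.167. Among them, ALDH1A1, an enzyme that makes retinoic acid, had a mean log2 level of 6.66 in periosteal against 4.47 in adipose cells (difference 2.19, SE 0.25). KCNT2 stood at 7.82 against 4.85 (2.97, SE 0.37), and the glutaredoxin pseudogene GLRXP1 at 9.05 against 7.41 (1.64, SE 0.21). On the adipose side, HMCN1, an extracellular matrix protein, had 3.90 in periosteal against 6.42 in adipose cells (difference -2.52, SE 0.33). DUXAP8 differed by -1.54 (SE 0.17) and CDIN1 by -0.89 (SE 0.12). BMP5, a bone morphogenetic protein, had 7.83 ± 0.55 against 5.42 ± 0.47 (2.41, SE 0.32; adjusted p = 0.167). SFRP1, a secreted WNT antagonist, had 9.22 ± 0.97 against 5.50 ± 0.03 (adjusted p = 0.635), and HES1, a Notch target, 5.91 ± 0.26 against 8.64 ± 1.19 (adjusted p = 0.45). By limma 0 genes passed; 2256 had an unadjusted p under 0.05, of which 800 were higher and 1456 lower in periosteal cells. The count was also 0 with an intensity trend and robust prior and 0 with ordinary least squares; it was 3 without periosteal replicate 3 and 2 without adipose replicate 1. The arrays of the 2 sites did not overlap for 4358 genes (13.2%), against 10% by chance.

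As a group, cell cycle genes ranked lower in periosteal than in adipose cells by camera, 1 of 4 lists out of 31 that passed. None of the 4 passed when the correlation between genes was estimated from the arrays (adjusted p = 0.78 with an estimated correlation for each). All 32 measured members were lower, with a median log2 difference of -1.29 (camera adjusted p = 7.33e-30), and 26 were lower by at least 2-fold. None was called over all genes, while 32 were adjusted over the list alone. MCM4, a replication helicase subunit, had 7.51 ± 0.28 against 8.65 ± 0.18. The list mean per array ran from -0.77 to 0.05 on periosteal and from 0.07 to 1.34 on adipose arrays. Skeletal muscle markers ranked higher in periosteal cells (14 of 14 members, median 0.44, adjusted p = 4.85e-06); this list stood at 1.25 on periosteal replicate 2 and at 0.16 and -0.17 on the other periosteal arrays. Interferon response genes (19 of 24 higher, median 0.38, adjusted p = 0.00768) and smooth muscle contractile genes (12 of 15, median 0.41, adjusted p = 0.0211) also ranked higher. Among contractile genes, DES, the muscle intermediate filament desmin, was at 10.63 on periosteal replicate 2 and at 7.51 and 6.71 on the other periosteal arrays. The muscle list was lost without periosteal replicate 2 (adjusted p = 0.057, median 0.17), and the interferon list without periosteal replicate 1 (0.638, median 0.029) or adipose replicate 3 (0.198); its median was 0.87 without periosteal replicate 2. The contractile list was lost without periosteal replicate 3 (0.0604), adipose replicate 2 (0.321, median 0.12) or adipose replicate 3 (0.301, median 0.13), and its median was 0.99 without adipose replicate 1. Of the 4 lists 3 were higher and 1 lower; without periosteal replicate 3 there were 2 higher and 5 lower, without adipose replicate 1 there were 6 and 2, and without adipose replicate 3 there was 1 of each. In the remaining lists a few members passed when adjusted over the list alone: HOXB7, MEIS2, ZIC1, HES1 and LMNB1 were lower, and BMP5 and CDKN2B higher, in periosteal cells.

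Between periosteal and dermal cells, KCNT2 was the gene that passed. Its mean log2 level was 7.82 ± 0.54 in periosteal and 2.75 ± 0.21 in dermal cells, a difference of 5.07 (SE 0.37) in the deposited values, with all periosteal arrays above all dermal ones (adjusted p = 0.00855). The dermal level lies under the lower quartile of every array and was not shown to be above background, so the size of the difference in transcript is uncertain. KCNT2 spans positions 196225779 to 196608440 of chromosome 1 (GRCh38.p14). BMP5 followed at 7.83 ± 0.55 against 5.05 ± 0.32 (2.78, SE 0.32; adjusted p = 0.0727). HOXB7, a homeobox gene of positional identity, had 6.39 ± 0.13 against 7.83 ± 0.12 (-1.44, SE 0.18; adjusted p = 0.134). MFAP5, a microfibril component, had 9.92 ± 1.42 against 5.05 ± 0.42 (4.87, SE 0.95; adjusted p = 0.611), and TNFAIP6, a hyaluronan-binding protein, 7.74 ± 0.28 against 5.24 ± 1.02 (adjusted p = 0.402). In all, 1 gene passed and 1862 had an unadjusted p under 0.05; arrays did not overlap for 3466 genes (10.5%, against 10% by chance). The KCNT2 call was lost without periosteal replicate 1 (adjusted p = 0.0863; 0.00222 to 0.406 over its alternatives), which left 0 genes. The number of genes was 2 without dermal replicate 3, 6 without dermal replicate 2 (2 higher and 4 lower in periosteal cells), 7 without adipose replicate 1, 8 without periosteal replicate 3 and 30 without dermal replicate 1. Other settings gave 5 genes from the arrays of these 2 sites alone, 4 with an intensity trend and robust prior and 0 without moderation.

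Of the 31 lists, 13 ranked higher in periosteal than in dermal cells by camera and none lower. None of the 13 passed with correlations estimated from the arrays (adjusted p = 0.142 to 0.599 with an estimated correlation). The estimated correlations of the osteogenic, stromal surface and endothelial lists (-0.0398, -0.014 and 0.00786) lay below the preset 0.01. A higher correlation therefore does not account for the loss of these calls. What else differs between the settings was not examined. Interferon response genes led (23 of 24 members higher, median log2 difference 0.72, adjusted p = 2.32e-10), with OAS1, an antiviral synthetase, at 6.53 ± 1.60 against 3.93 ± 0.21. NF-kB and inflammatory genes followed (16 of 20, median 0.49, adjusted p = 1.2e-06); TNFAIP6 and LIF were called when adjusted over the list alone. Genes of fibrillar and basement membrane matrix were higher in 34 of 42 cases (median 0.41, adjusted p = 1.82e-06), although TNC, a matrix glycoprotein, had 6.41 ± 0.26 against 9.12 ± 1.41. Skeletal muscle markers were higher in 14 of 14 cases (median 0.39, adjusted p = 1.82e-06), with CHRNA1, the muscle acetylcholine receptor subunit, at 7.51 ± 2.51 against 4.80 ± 0.02; on periosteal replicate 2 it was at 10.14. Mesenchymal stromal surface markers (10 of 12, median 0.62, adjusted p = 0.000613) included ITGA11, a collagen receptor, at 8.90 ± 1.48 against 5.38 ± 0.83. Notch signalling genes (13 of 15, adjusted p = 0.000888) and osteogenic genes (11 of 19, adjusted p = 0.00876) passed too; among the latter OMD, a bone proteoglycan, had 6.08 ± 1.61 against 3.55 ± 0.60. The remaining lists were chondrogenic genes (adjusted p = 0.00876), BMP and TGF-beta signalling (0.0114), endothelial markers (0.0223), senescence-associated genes (0.0237), dermal fibroblast genes (0.0253) and hypoxia and glycolysis (0.0444). In the dermal fibroblast list, the members called when adjusted over the list alone were MFAP5 and SFRP2, a WNT modulator; in the chondrogenic list they were COL11A1 and PRG4, in BMP signalling BMP5. No member of any list was called over all genes.

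Of the 13 lists, fry, a rotation test, called 1, the osteogenic list (adjusted p = 0.0289). The median difference of interferon genes was 0.28 without periosteal replicate 1 and 1.24 without periosteal replicate 2, and that of NF-kB genes 0.31 without periosteal replicate 3. It was 0.20 for matrix genes without dermal replicate 3. For skeletal muscle markers it was 0.094 without periosteal replicate 2 and 0.60 without periosteal replicate 3, and for stromal surface markers 0.37 without periosteal replicate 1 and 0.23 without dermal replicate 3. While 7 lists passed in all 9 leave-outs, 6 did not. Hypoxia and glycolysis was lost without periosteal replicate 1 (adjusted p = 0.101), periosteal replicate 2 (0.162), dermal replicate 1 (0.313) or dermal replicate 2 (0.623). Endothelial markers were lost without periosteal replicate 1 (0.101), dermal replicate 1 (0.13) or dermal replicate 2 (0.0551). BMP and TGF-beta signalling was lost without periosteal replicate 3 (0.114), dermal replicate 1 (0.0866) or dermal replicate 2 (0.0551), and senescence-associated genes without the same arrays (0.143, 0.0866 and 0.101). Dermal fibroblast genes were lost without periosteal replicate 3 (0.0681), dermal replicate 2 (0.101) or dermal replicate 3 (0.381), and chondrogenic genes without dermal replicate 1 (0.0866) or dermal replicate 3 (0.0692).

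**Figure D1:**
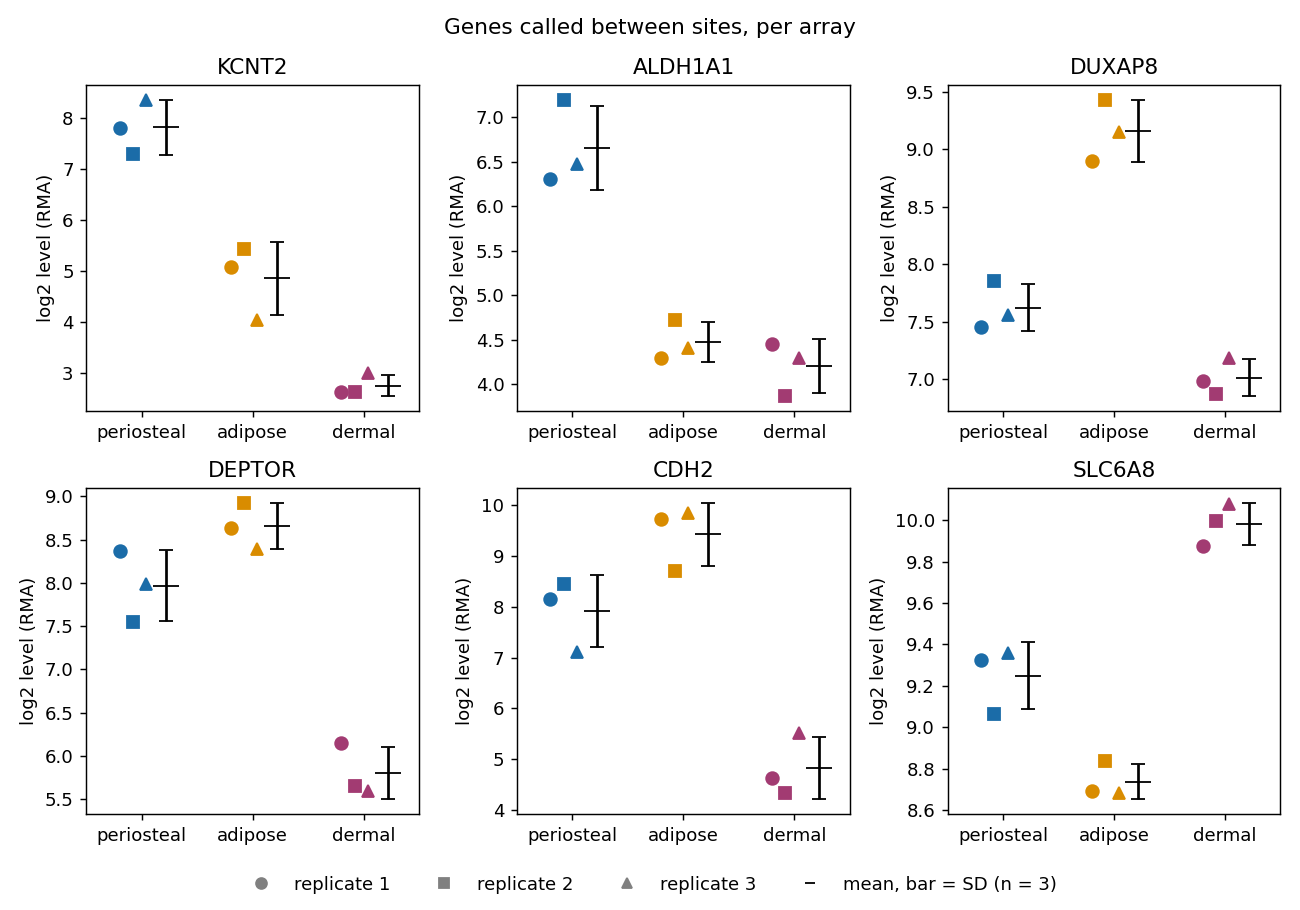
Log2 level (RMA) of the 6 genes called between sites, with 1 marker per array, the mean as a horizontal line and the SD as a bar (n = 3 per site). KCNT2 lies highest on the periosteal and lowest on the dermal arrays (means 7.82 and 2.75), and CDH2 is lowest on the dermal arrays (mean 4.82).

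Adipose and dermal cells, both of soft tissue, differed in 4 genes. CDH2, which encodes N-cadherin, was higher in adipose cells (9.43 ± 0.62 against 4.82 ± 0.62; log2 difference of deposited values 4.61, SE 0.45, adjusted p = 0.024); its dermal level is near the array medians, so the size is uncertain. DEPTOR was 7.21-fold higher (8.65 ± 0.27 against 5.80 ± 0.30; 2.85, SE 0.24, adjusted p = 0.0143). DUXAP8 was 4.43-fold higher (9.16 ± 0.27 against 7.01 ± 0.16; 2.15, SE 0.17, adjusted p = 0.0143). SLC6A8, the creatine transporter, fell by 1.25 on the log2 scale in adipose relative to dermal cells (8.74 ± 0.09 against 9.98 ± 0.10; SE 0.12, adjusted p = 0.024). For each of these, the 3 adipose arrays lay apart from the 3 dermal ones. DUXAP8 and SLC6A8 have closely related copies elsewhere in the genome, so their probes could also read those. In GRCh38.p14, CDH2 lies on chromosome 18 (27932879 to 28177130), DEPTOR on chromosome 8 (119873722 to 120050918), DUXAP8 on chromosome 22 (15784954 to 15827434) and SLC6A8 on chromosome X (153687926 to 153696593). Larger differences did not pass: PRG4, the joint lubricant lubricin, had 10.52 ± 1.26 against 4.63 ± 0.76 (adjusted p = 0.29), and MFAP5 10.35 ± 1.95 against 5.05 ± 0.42 (adjusted p = 0.299).

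With 3 genes higher and 1 lower in adipose cells, 2339 genes had an unadjusted p under 0.05, and arrays did not overlap for 3698 (11.2%, against 10% by chance). DEPTOR and DUXAP8 were lost without adipose replicate 2 (adjusted p = 0.0869 and 0.077), adipose replicate 3 (0.0797 for both) or dermal replicate 3 (0.0947 and 0.0798). CDH2 and SLC6A8 were lost without periosteal replicate 1 (0.0939 for both), adipose replicate 2 (0.077 and 0.13), adipose replicate 3 (0.11 for both) or dermal replicate 3 (0.0798 and 0.155). CDH2 was also lost without periosteal replicate 2 (0.052) and SLC6A8 without periosteal replicate 3 (0.055). Over all alternatives the adjusted p ran from 0.0067 to 0.182 for DEPTOR, 0.0067 to 0.127 for DUXAP8, 0.0218 to 0.312 for CDH2 and 0.018 to 0.155 for SLC6A8. The count was 0 without adipose replicate 2, adipose replicate 3 or dermal replicate 3, and 2 without periosteal replicate 1. It was 16 without dermal replicate 2 (6 higher and 10 lower in adipose cells), 18 without adipose replicate 1 and 47 without dermal replicate 1. Over all probe sets, named or not, 9 passed; 2 genes passed with an intensity trend and robust prior, 1 from the arrays of these sites alone and 0 without moderation.

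Cell cycle genes ranked higher in adipose than in dermal cells by camera, a call lost with an estimated correlation (adjusted p = 0.155 with an estimated correlation). None of the 15 lists that passed kept its call in that setting (adjusted p = 0.155 to 0.491 with an estimated correlation). For the osteogenic, stromal surface, osteoclast, angiogenic and protease lists the estimated correlations (-0.0549 to 0.00711) lay below the preset 0.01. A higher correlation does not account for their loss. For the cell cycle list, all 32 members were higher, with a median log2 difference of 1.28 (camera adjusted p = 1.35e-26), and 25 were called when adjusted over the list alone. TOP2A and MKI67, both markers of proliferation, differed by 1.75 and 1.78. The list mean per array ran from 0.07 to 1.34 on adipose and from -0.83 to 0.01 on dermal arrays. Matrix genes were higher in 37 of 42 cases (median 0.45, adjusted p = 3.81e-07), with COL1A1, the main bone and skin collagen chain, at 12.34 ± 0.44 against 11.01 ± 0.79. NF-kB and inflammatory genes (17 of 20 higher, adjusted p = 0.000274) included TNFAIP6 at 8.31 ± 0.40 against 5.24 ± 1.02. BMP and TGF-beta signalling (21 of 29, adjusted p = 0.00279) had SMAD7, TGFB1 and TGFBR1 called when adjusted over the list alone. Interferon response genes (17 of 24, adjusted p = 0.00578) and dermal fibroblast genes (12 of 15, adjusted p = 0.0117) were higher, the latter with MFAP5 and SFRP2 called over the list alone. Immediate early and heat shock genes (adjusted p = 0.0283), angiogenic factors (0.0334), matrix proteases and inhibitors (0.0334) and Notch signalling (0.0338, with HES1 at 8.64 ± 1.19 against 4.91 ± 0.64) passed as well. Mesenchymal stromal surface markers, osteogenic genes, chondrogenic genes and other positional transcription factors were higher, and osteoclast and mature osteocyte markers lower, each with adjusted p = 0.0354. Among positional factors, ZIC1, GATA6, MEIS2 and IRX3 were called when adjusted over the list alone, all higher in adipose cells. No member of any list was called over all genes.

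The cell cycle, matrix, NF-kB and BMP lists, 4 of the 15, passed in all 9 leave-outs; the median of the matrix list was 0.70 without adipose replicate 2, 0.73 without dermal replicate 2 and 0.28 without dermal replicate 3. Without adipose replicate 1 the osteogenic, stromal surface, osteoclast, angiogenic, positional and Notch lists were lost (adjusted p = 0.0682 to 0.616). Without adipose replicate 2 the osteogenic, interferon, protease, stromal surface and osteoclast lists were lost (0.0534 to 0.0914). Without adipose replicate 3 the osteoclast, dermal fibroblast, osteogenic, angiogenic, positional, chondrogenic and immediate early lists were lost (0.0579 to 0.863), leaving 8. Without dermal replicate 1 the osteogenic, immediate early, Notch, osteoclast and chondrogenic lists were lost (0.0754 to 0.251). Without dermal replicate 2 the osteogenic, osteoclast, Notch, angiogenic, stromal surface, protease and positional lists were lost (0.0554 to 0.298), and 9 passed. Without dermal replicate 3 the immediate early, interferon, positional, osteogenic, stromal surface, dermal fibroblast, protease and chondrogenic lists were lost (0.0644 to 0.181), and 8 passed.

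**Figure D2:**
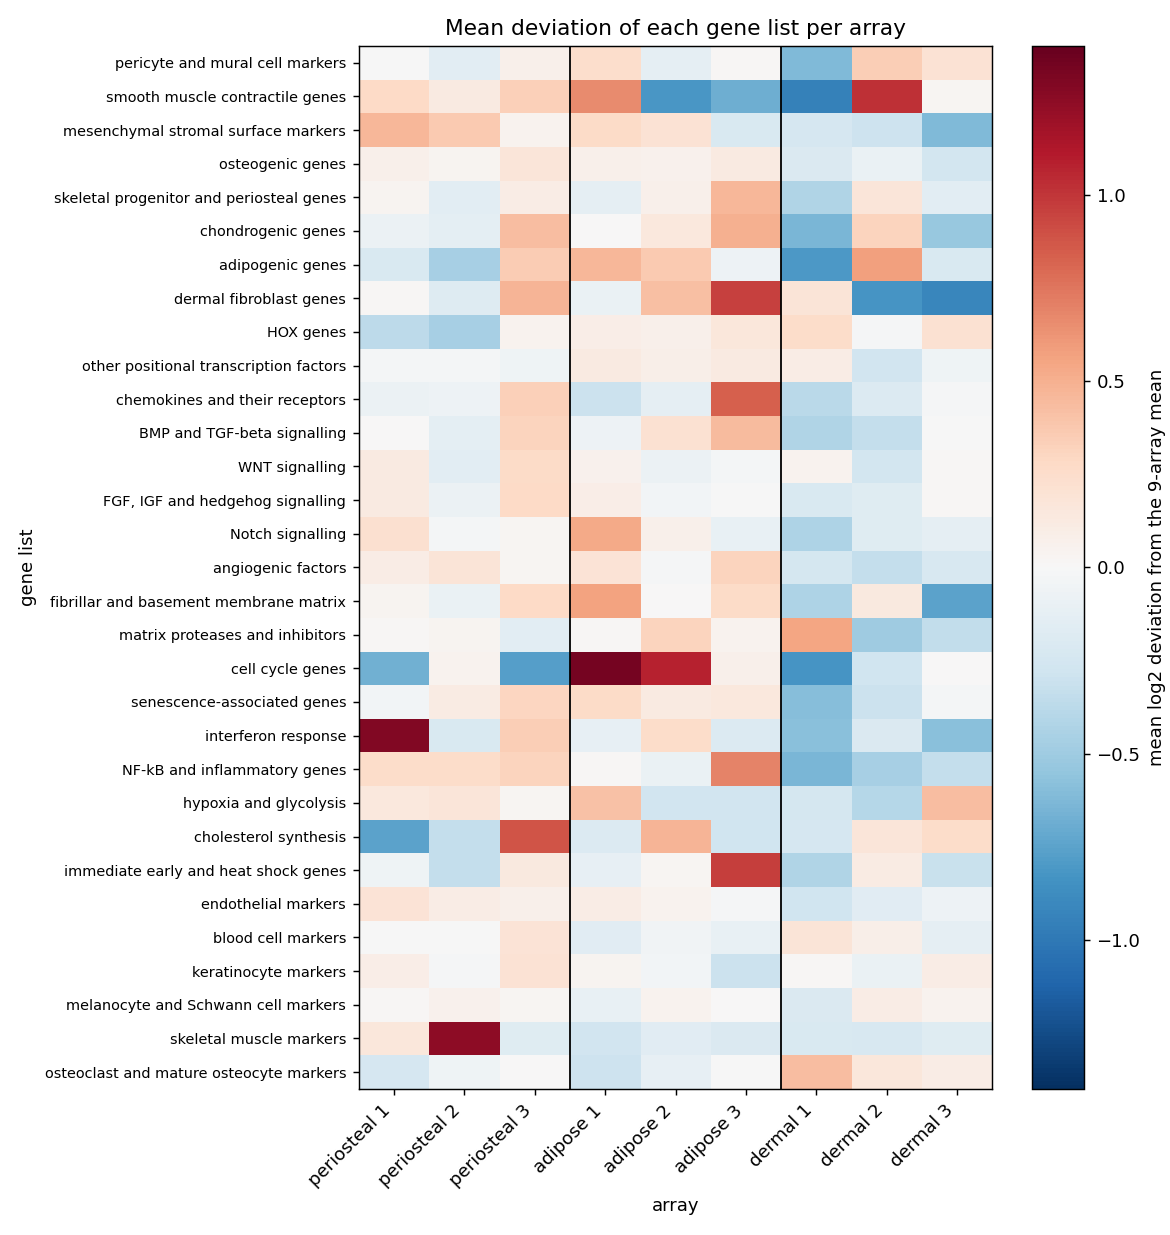
Mean log2 deviation of each of the 31 gene lists (vertical axis) on each of the 9 arrays (horizontal axis) from its mean over all arrays, red for higher and blue for lower. The cell cycle list is highest on adipose replicate 1 (1.34), the interferon list on periosteal replicate 1 (1.29) and the skeletal muscle list on periosteal replicate 2 (1.25).

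Periosteal cells were then set against the mean of both soft tissues. KCNT2 was higher in periosteal cells (log2 difference of deposited values 4.02, SE 0.32, adjusted p = 0.0182), with the same limit on its size from the low dermal level. ALDH1A1 was higher too (6.66 ± 0.47 against 4.47 ± 0.22 in adipose and 4.20 ± 0.31 in dermal cells; 2.32, SE 0.22, adjusted p = 0.0362); both soft-tissue levels lie below the array medians, so this size is uncertain too. ALDH1A1 spans positions 72900671 to 72953053 of chromosome 9 (GRCh38.p14). For both genes the 3 periosteal arrays lay above the other 6. BMP5 did not pass (2.60, SE 0.27, adjusted p = 0.0653), nor did HOXB7 (-1.24, SE 0.16, adjusted p = 0.191). In total 2 genes passed and 1964 had an unadjusted p under 0.05; all 3 periosteal arrays lay outside the other 6 for 866 genes (2.62%, against 2.38% by chance). ALDH1A1 kept its call in 1 of 9 leave-outs: it was lost without periosteal replicate 1 (adjusted p = 0.072), 2 (0.079) or 3 (0.0581), adipose replicate 1 (0.0561), 2 (0.0588) or 3 (0.201), and dermal replicate 2 (0.0614) or 3 (0.109). It was also lost when the probe sets of a gene were averaged (log2 difference 1.19, adjusted p = 0.127; 0.0174 to 0.655 over its alternatives). KCNT2 was lost without periosteal replicate 1 (0.072) or 2 (0.0652; 0.00895 to 0.655 over its alternatives). The number of genes was 0 without either of those arrays, 1 without adipose replicate 2 or 3, 5 without adipose replicate 1 or dermal replicate 1 and 7 without periosteal replicate 3.

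Of the lists, 5 passed by camera. All 5 were lost with correlations estimated from the arrays (adjusted p = 0.398 with an estimated correlation). For the stromal surface list that correlation (-0.014) lay below the preset 0.01, so a higher correlation does not account for its loss. Cell cycle genes ranked lower in periosteal cells (32 of 32 members, median log2 difference -0.67, adjusted p = 9.54e-15), with E2F1 and MCM4 called when adjusted over the list alone. Against dermal cells alone this list did not pass (12 higher and 20 lower, median -0.08, adjusted p = 0.371), and its mean was -0.47 on periosteal, -0.37 on dermal and 0.83 on adipose arrays. Interferon response genes (21 of 24 higher, median 0.65, adjusted p = 3.56e-08) and skeletal muscle markers (14 of 14, median 0.44, adjusted p = 3.56e-08; list mean 1.25 on periosteal replicate 2) ranked higher, as did NF-kB and inflammatory genes (15 of 20, adjusted p = 0.00313), among them LIF at 8.47, 7.27 and 6.92 in periosteal, adipose and dermal cells. Mesenchymal stromal surface markers ranked higher too (10 of 12, adjusted p = 0.0103), a call lost without periosteal replicate 1 (0.0868). Against adipose cells alone, neither the NF-kB list (adjusted p = 0.67) nor the stromal surface list (adjusted p = 0.521) passed. The interferon list mean was 1.29 on periosteal replicate 1 and -0.22 and 0.34 on the other periosteal arrays; without replicate 1 its median was 0.16 (interferon response adjusted p = 0.00663). Without periosteal replicate 2 the median of the skeletal muscle markers was 0.11. HOX genes did not pass (adjusted p = 0.19; 12 higher and 11 lower, with a median of 0.01 and a mean of -0.40); HOXB7, HOXC8, HOXC9 and HOXC10 were called, all lower, when adjusted over the list alone. On genes chosen without each array, 2 periosteal arrays projected at or below the highest soft-tissue array. Pericyte and mural cell markers (adjusted p = 0.818), skeletal progenitor and periosteal genes (0.462) and adipogenic genes (0.3) did not pass either. The number of lists was 8 without dermal replicate 2, 9 without periosteal replicate 2 or dermal replicate 3, 10 without periosteal replicate 3 (6 higher and 4 lower) and 11 without adipose replicate 1. Over the 4 comparisons no list that passed differed in sign between its test, median and mean; among those that did not pass, 8, 3, 5 and 9 did, in the order given here.

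Genes that mark 1 site against both others were sought in the pairs of comparisons that share a site. By limma, 0 genes passed in both comparisons of any site. At an unadjusted p under 0.05, the largest set was 532 genes higher in adipose than in both other sites. Over 100 simulations of 9 arrays with no site difference and with independent genes, the mean was 191 and the highest 243. Independent lists would share 55.3 genes. Periosteal cells had 199 higher and 272 lower genes (simulated highest 224 for each) and dermal cells 270 higher and 243 lower (simulated highest 233 and 231); 212 genes were lower in adipose cells (simulated highest 225). Independent lists would share 19.2 and 47 genes for periosteal, 35 and 30.1 for dermal and 26.2 for lower in adipose cells. The simulations include the sharing of arrays, which alone gave means of 189.7 to 193.1 genes per set. The sets of 199 and 212 genes lay below their simulated highest. Genes were simulated as independent, so the simulated highest is not a bound on chance for correlated genes. Whether the other sets exceed chance is therefore not decided. The count of 0 became 3 without periosteal replicate 3, 3 without adipose replicate 1, 4 without dermal replicate 2 and 20 without dermal replicate 1. With an intensity trend and robust prior it was 1, DEPTOR, low in dermal cells; without moderation it was 0.

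Several gene groups differed as much between arrays of a site as between sites. Among periosteal arrays, the homeobox gene HOXC10 stood at 4.21, 3.71 and 8.60 on replicates 1, 2 and 3, against 8.69 to 9.94 on the soft-tissue arrays. The interferon list mean was 1.29 on periosteal replicate 1 and -0.22 and 0.34 on the others. Smooth muscle contractile genes ran from -0.95 on dermal replicate 1 to 1.02 on dermal replicate 2. Cholesterol synthesis genes ranged from -0.75 to 0.88 among periosteal arrays. Of the 31 lists, those of pericyte markers, skeletal progenitor genes, adipogenic genes, HOX genes, chemokines, WNT signalling, FGF, IGF and hedgehog signalling, cholesterol synthesis, blood cells, keratinocytes, and melanocytes and Schwann cells did not pass in any comparison (smallest adjusted p = 0.0949, keratinocyte markers).

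**Figure D3:**
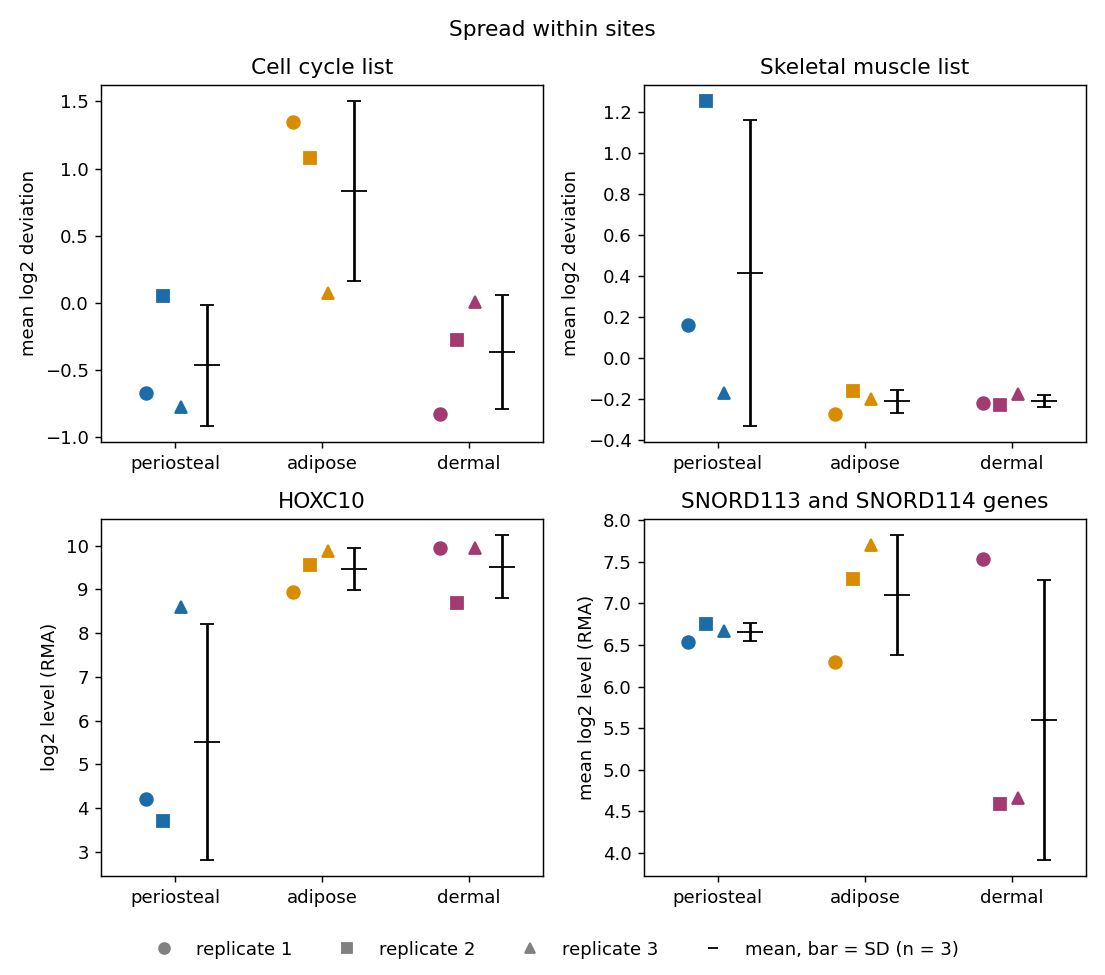
Spread within sites of the cell cycle and skeletal muscle lists (mean log2 deviation), HOXC10 (log2 level) and the SNORD113 and SNORD114 small nucleolar RNA genes (mean log2 level), with 1 marker per array, the mean as a horizontal line and the SD as a bar (n = 3 per site). The muscle list is at 1.25 on periosteal replicate 2, and the SNORD113 and SNORD114 mean is 4.59 and 4.67 on dermal replicates 2 and 3.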

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

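Array quality weights were chosen after the results were seen; the other alternatives were planned. Over 17 alternatives or fewer per result, the named genes' differences kept direction and side of the threshold in 2389 cases, most of them without a call to lose. There were 48 lost and 9 gained calls, and 23 differences changed sign, each with a limma adjusted p of at least 0.877. The called genes were less stable. KCNT2 kept its call in 14 of 17 alternatives against dermal cells and 12 of 16 against both soft tissues. ALDH1A1 kept its call in 5 of 16. Between adipose and dermal cells, DEPTOR and DUXAP8 kept theirs in 11 of 17, and CDH2 and SLC6A8 in 8 of 17. PTPRC and other genes below the median level have no value where dim genes were left out. The cause was not tested for the changes below, except where fewer arrays or features entered the fit. The replicate numbers did not pair the samples across all 3 sites: 1 of 9 same-number pairs had deviations correlated over 0.1 (range -0.262 to 0.172), and 2 of 9 arrays correlated best with their own number. Between periosteal and adipose arrays, same-number correlations (0.172, 0.0569 and 0.0819) lay above all others (-0.126 to 0.0507). Same-number pairs with dermal arrays were all negative (-0.262 to -0.0631). A pairing of periosteal with adipose arrays is therefore not excluded. With the replicate block, 0 genes passed for periosteal against dermal, 0 for adipose against dermal, 0 for periosteal against both soft tissues and 0 by the F-test, and 9 lists passed for periosteal against both soft tissues; the block changed no other count by over 1.5 times. For periosteal against both soft tissues, 8 lists passed with arrays centred, 8 with dim genes left out and 8 with array weights, 1 gene passed with the mean of a gene's probe sets and 4 features over all probe sets. Over all probe sets, 9 passed for adipose against dermal and 6 by the F-test. An intensity trend and robust prior gave 4 genes for periosteal against dermal, 2 for adipose against dermal, 5 by the F-test and 1 marking a site. Ordinary least squares without moderation gave 0 in both of these contrasts, 0 for periosteal against both soft tissues and 0 by the F-test. The arrays of the compared sites alone gave 5 for periosteal against dermal and 1 for adipose against dermal, and array weights 2 and 2. With an estimated correlation, camera called 0 lists in each of the 4 comparisons (1, 5, 9 and 2 at an unadjusted p under 0.05), and fry called 0, 1, 0 and 0 (1, 4, 7 and 3 unadjusted).

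With each array left out in turn, the number of genes ran from 0 to 3 for periosteal against adipose, 0 to 30 for periosteal against dermal, 0 to 47 for adipose against dermal, 0 to 7 for periosteal against both soft tissues, 0 to 39 by the F-test and 0 to 20 marking a site. The highest counts came without dermal replicate 1, except for periosteal against adipose and against both soft tissues (without periosteal replicate 3). Lists ran from 2 to 8, 9 to 15, 8 to 15 and 4 to 11 in the 4 comparisons. Sign changes touched small differences. CXCR4 went from -0.14 to 0.11 for periosteal against adipose, from -0.018 to 0.091 against dermal and from -0.0598 to 0.087 against both soft tissues, and from -0.0896 to 0.16 for adipose against dermal. For adipose against dermal, PECAM1 ran from -0.15 to 0.11, PTPRC from -0.12 to 0.091, ERBB3 from -0.023 to 0.18 and CXCL12 from -0.11 to 0.69; for periosteal against dermal, CXCL12 ran from -0.59 to 0.21. CXCR4 between periosteal and adipose was -0.0019 after quantile normalization again and -0.00098 with arrays centred, and TBX18 between adipose and dermal 0.011 with the mean of its probe sets. No background level was used here, so small differences of dim genes are limited by signal over background: KCNT2 in dermal cells (2.75) lay under the lower quartile of the arrays (3.39 to 3.41).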

Other observations

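Tests marked as later ones in this part were chosen after the result was seen: those of the cell cycle list by site and by culture, of the muscle list by site and against the soft-tissue arrays, of single genes for the HOXC pattern (shares and genes called without an array), and the comparisons of the small nucleolar RNAs and keratins. The small nucleolar RNAs of the SNORD113 and SNORD114 families, which lie in an imprinted cluster on chromosome 14 (100924821 to 100993309, GRCh38.p14), had a mean log2 level of 4.59 and 4.67 on dermal replicates 2 and 3, and of 6.30 to 7.71 on the other 7 arrays. Of 39 measured members, 35 were lower on both of those arrays than on each of the other 7, against 2.60% of all genes, with a median difference of -2.59. MEG8, a long noncoding RNA of the same cluster, stood at 5.31 and 5.22 on those arrays, and at 7.60 to 9.19 on the others. MEG9 did not share this (8.05 and 7.92, against 7.97 to 8.14). Of the paternally expressed genes, RTL1 was also lower on both of those arrays (3.78 and 3.61, against 3.91 to 4.48), all below the array medians, while DLK1 was not (4.85 and 5.46, against 4.89 to 5.40). Another pair of dermal arrays, replicates 1 and 3, carried high levels of the hair keratin gene KRT34 (10.91 and 10.94, against 7.01 to 7.96 on the other 7) and of KRT31 (8.38 and 8.40, against 6.40 to 6.90). EBF2, a preadipocyte transcription factor, was at 4.42 on dermal replicate 1 against 9.76 to 10.81 on the other arrays. No explanation was tested for these patterns.

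Cell cycle genes ranked lower in periosteal than in adipose cells by camera, a call lost with an estimated correlation (adjusted p = 0.78 with an estimated correlation). Scaling between arrays that depends on intensity is argued against: the list's median of -1.29 lay at percentile 0 of 10000 random lists matched on level, whose central range was -0.13 to 0.055. A difference carried by every adipose culture stays open, since the lowest adipose array stood 0.022 above the highest of the other 6, less than the SD within sites of 0.53. The growth state of single cultures at harvest could also produce it: the range of list means within a site (1.27) was of the size of the difference between sites (1.30), a gap of -0.024. Site and growth state cannot be told apart with 3 cultures per site.

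Skeletal muscle genes ranked higher in periosteal cells than in both soft tissues by camera, a call lost with an estimated correlation (adjusted p = 0.398 with an estimated correlation). By this list alone, a site effect on every culture stays open. On it, 2 of 3 periosteal arrays lay above the other 6. The third (-0.17) lay above 5 of them and 0.0098 below the highest (-0.16), less than their SD of 0.039. An earlier bound of this later test counted such a value as an argument against a site effect. That bound was changed after the value was seen, because the gap was less than the SD. Muscle-lineage cells in the culture of periosteal replicate 2 are a candidate explanation: a second list of muscle genes, sharing none with the first, reached percentile 100 of matched lists there (mean deviation 1.26; 23 of 32 genes highest on that array; ACTC1 at 11.17, DES, of the contractile list, at 10.63, TTN at 9.80), although such cells would have had to pass the gate, which kept CD146 positive cells and removed CD31 and CD45 positive ones; 27 of its 32 genes had a mean over the 9 arrays above the median level of all probe sets. For replicate 1 the same test gave percentile 85.94, short of the top 2.5% of matched lists, which had been set beforehand as an argument against; that bound was judged wrong after the value was seen, because centring on all 9 arrays includes replicate 2, and the question is left open. Against the 6 soft-tissue arrays, a later test, the second list on replicate 1 reached percentile 99.72 (difference 0.22). On periosteal replicate 3 the second list had a mean deviation of -0.22, within the range of the soft-tissue arrays (-0.27 to -0.037). The second list thus gave no sign of a site effect on that culture.

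HOXC genes were low on 2 of 3 periosteal arrays, below the other 7 in 4 of 6 HOXC genes, while 0 of 17 HOXA, HOXB and HOXD genes put those arrays outside. A soft-tissue library under a periosteal label stays open: on genes chosen without each array, the lowest periosteal projection lay -0.4148 from the highest soft-tissue one (0.24 against 0.66), with 2 periosteal arrays at or below that and 3 soft-tissue arrays at or above the lowest periosteal one. Against it, all 3 periosteal arrays lay apart from the 6 soft-tissue ones for KCNT2 (lowest 7.29 against highest 5.44), ALDH1A1 (6.31 against 4.72), BMP5 (7.29 against 5.94) and HOXB7 (highest 6.50 against lowest 7.16), although ALDH1A1, BMP5 and HOXB7 were ranked with all arrays in the fit. The periosteal array with soft-tissue HOXC levels had that lowest projection. Of 6 genes other than HOX genes called without it, 1, KCNT2, put it beyond the soft-tissue arrays. So did 38% of the 50 genes chosen without it, within the 34% to 74% of left-out soft-tissue arrays (40%, 40% and 40.5% with 20, 100 and 200 genes, also within their ranges). These shares decide nothing, because left-out periosteal arrays reached at most 76%. A left-out soft-tissue array was also set against fewer soft-tissue arrays. The projection decides nothing either, because it did not separate the sites. Left-out soft-tissue arrays ran from 0.0033 to 0.66 and left-out periosteal arrays from 0.24 to 0.91. A positional program shared with other transcription factors was not decided: 2 of 39 (5.13%) put the same arrays outside, equal to the median of matched lists, which met the bound set beforehand as an argument against, but the exact binomial upper 95% limit of 17.3% exceeds the 12.8% that bounds the top 2.5% of matched lists, so it was judged after the value was seen to decide nothing; tissue of origin within the periosteum was not tested.

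Splits of the same arrays into groups of the same sizes tested whether chance can be excluded; every count of splits below includes the real one. For the F-test, 5 of 100 splits gave at least the real 3 genes (highest other 17), so chance is not excluded. For periosteal against both soft tissues it is not excluded either, with 7 of 100 splits for genes (real 2, highest other 8) and 59 of 100 for lists (real 5, highest other 17). For genes marking a site the real count of 0 is reached by all 100 of 100 splits by construction (highest other 11), so that test decides nothing. For pairs of sites the 10 splits are too few for a share under 0.05. There, at least the real number of genes came from 1 split, the real one, for periosteal against dermal (real 1, highest other 0) and from 2 for adipose against dermal (real 4, highest other 51); for periosteal against adipose the real count of 0 is again reached by all 10 (highest other 3). At least the real number of lists came from 8 splits for periosteal against adipose (real 4, highest other 8), and from the real split alone, 1 of 10, for periosteal against dermal (real 13, highest other 10) and for adipose against dermal (real 15, highest other 7). The split that called 51 genes set adipose replicate 1 and dermal replicates 2 and 3 against the other adipose and dermal arrays. This points to a structure of the samples, but the split was picked for its count and its genes were not examined. The SNORD113 and SNORD114 means divide these arrays in the same way (6.30, 4.59 and 4.67 against 7.29, 7.71 and 7.54). Whether genes of that cluster or many others carry the count was not tested.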
